A study of Mus musculus with 6 samples.

How the data were processed

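The series holds 6 RNA sequencing libraries from the dorsal root ganglia of wild-type C57BL/6J mouse embryos at embryonic day 14.5. Ganglia of 18 embryos were pooled, and total RNA of that pool was diluted from a stock of 100 ng per µl. Per the labels, cDNA was made with SMARTer low-input kits, which prime on the poly(A) tail and copy the full transcript by template switching. In the high-volume group the RNA entered the reaction in 9 µl, and in the low-volume group in 1 µl, with a kit for each, so the reaction volume and the kit cannot be separated. Each volume was run at 3, 10 and 30 ng of RNA, with 1 library for each combination of volume and input. The cDNA was sheared for 3 min, and the library PCR had 12 cycles. Replicates 1, 2 and 3 of each volume are the 10, 3 and 30 ng libraries. All 6 libraries are technical repeats of 1 RNA pool, so every SD, SE and p-value measures technical spread and none measures spread between animals.

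Per the submitters' processing notes, CASAVA 1.8, TopHat2 2.0.8 and Bowtie2 2.1.0 were used with the GRCm38.p1 genome build. The counting program, the treatment of reads with several matches and the annotation release are not given in the sources used here. The deposited files hold, for each transcript, exon and intron, a whole-number read count called a tag count, and the authors' RPKM, which is that count scaled to the feature length in kilobases and to the total tags of the library. The count of each of the 93615 transcripts equalled the sum of its exon counts. The 22 exon intervals that occur on both strands carried the same count on each strand in the high-volume 10 ng library, the only library checked. Intervals without tags were not set aside in this check. The counts were therefore taken not to use strand, so that tags of overlapping or antisense genes cannot be told apart. In total 5578 genes shared exonic bases with another gene. Coordinates are 1-based on GRCm38.

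Transcripts were assigned to genes with the GENCODE M21 annotation of GRCm38, which matched 89664 transcripts, 86.1% of them with identical coordinates. The 3951 unmatched transcripts stayed out of the gene tests. Each of the 37086 genes was represented by the transcript with the largest count summed over the libraries, for its count and for its RPKM. Reads can belong to several transcripts of a gene, so transcript counts were not summed. The chosen transcripts held 14160401 to 31524211 tags per library. Tags carry no molecular identifiers, so PCR copies and separate molecules cannot be told apart.

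Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test with TMM scaling and the filterByExpr filter, which left 16120 genes. The model held the reaction volume and centred log2 input and left 3 residual degrees of freedom. A model with their interaction left 2. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. SEs of log2 differences were derived from the quasi-likelihood F statistic. CPM values in the text are tags scaled to the sum over the chosen transcripts, without TMM factors unless said. Lists of genes (24, each with at least 5 measured members) were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with the correlation between genes preset to 0.01, and again with an estimated correlation. Camera tests a list against the other genes, while fry, run as an alternative, tests it against no change, so their counts answer different questions. With an estimated correlation camera uses the residual degrees of freedom of the fit. These are 3 in the 6 libraries and 1 in the 10 and 30 ng libraries. With the preset it uses a number set by the genes. The version with an estimated correlation thus has little power here, and a list that fails it is not shown to be unchanged. The lists were sensory neurons, the nociceptor lineage, the mechanoreceptor and proprioceptor lineage, glia, cell cycle, endothelium, fibroblasts and meninges, pericytes and smooth muscle, erythroid cells, macrophages, cartilage and bone, skeletal muscle, spinal cord, sympathetic and chromaffin cells, epidermis, Hox genes, replication-dependent histones, cytosolic ribosomal proteins, protein-coding genes of the mitochondrial genome, nuclear genes of oxidative phosphorylation, small structured RNAs, immediate-early and stress genes, nuclear long noncoding RNAs and reference genes.

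Levels were described with the deposited RPKM as mean, SD and range over 6 libraries. The 9 pairs of genes were compared on log2(RPKM + 1) by a two-sided exact sign-flip permutation test, whose smallest p is 0.0312. Some genes and pairs are not reported here. A fold on that scale understates the ratio of genes with low values. Measures with 1 value per library were compared between volumes with a two-sided exact permutation test, whose smallest p is 0.1, so that no such test could pass the threshold. Detected genes had 5 or more tags after every library was thinned to 14160401 tags, as the mean of 10 draws. Coverage along transcripts was the log2 ratio of tags per base in exons of the 5′ part to those of the 3′ part in 8699 protein-coding transcripts with at least 5 exons and 600 summed tags. Intron tags were taken from the 155594 introns of chosen transcripts that overlap no exon. Correlations across genes describe libraries, and genes are not independent replicates.

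The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took the 12 highest and the 12 lowest log2 differences past the threshold with a mean CPM of 10 or more, the same sign in each pair of libraries and a symbol that is no clone or pseudogene name, the 5 genes with the lowest interaction p, and for each list up to 4 members past the threshold or else the 2 with the highest CPM. Where the fit of the 10 and 30 ng libraries is described, the same rule was applied to that fit after its count was seen.

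Alternatives fixed in advance were other scalings (RLE, total count), other filters (none, mean CPM of 5), DESeq2 1.42.0, limma-voom, the input as a replicate block with and without a length correction, no input term, the longest transcript, the sum over distinct exons, thinned libraries, each library left out in turn and the 10 and 30 ng libraries alone. Added after the data were seen were voom with a quality weight per library, a fit without Gm42418, GC and length corrections by loess (span 0.5) in the 10 and 30 ng libraries, input in those libraries, and camera with the block or in those libraries. Libraries of the same input were treated as pairs only after a check: their deviations from the means of their volume correlated across genes at r = 0.111 for 10 ng, 0.132 for 3 ng and 0.127 for 30 ng, each above 0.1. The input was used as a pairing factor in the alternatives with a replicate block and in the fit of the 10 and 30 ng libraries. The main fit used log2 input as a slope and did not pair the libraries. Of the 6 pairs of unlike input, high-volume 10 ng with low-volume 30 ng was at 0.103 and the others at -0.132 to 0.0665, so the check does not part 10 from 30 ng clearly.

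The procedure was tested on simulated counts with the means and sizes of these libraries. With 6 libraries, 43% of genes given a log2 volume difference of 1 and 88% of those given 2 were called (15514 genes tested), with 7 false calls among 138. For input, 59% of genes with 0.5 per doubling and 98% of those with 1 were called (15539 genes), with 5 false calls among 162. For the interaction, 64% of genes with 1 and 99% with 2 were called (15555 genes), with 15 false calls among 178. With the 10 and 30 ng libraries, 90% and 100% of genes with volume differences of 1 and 2 were called (15919 genes). There were 20 false calls among 210. These shares describe the simulated counts, and whether those had the spread of the data was not tested. In the data the edgeR coefficient of variation between libraries was 0.391 over 6 libraries and 0.144 in the 10 and 30 ng libraries. Over 6 libraries Gm42418 passed at a log2 volume difference of 1.56. Iscu at 2.10 and Med30 at 1.99 did not (edgeR adjusted p = 0.327 for each). The 88% is therefore not shown to hold for the 6 real libraries.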

Results

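RNA from 1 pool of embryonic mouse dorsal root ganglia, the clusters of sensory neurons and glia beside the spinal cord, was sequenced as 6 libraries to compare 2 reaction volumes, each with its own low-input kit, at 3 amounts of RNA. The high-volume group and the low-volume group each held 3 libraries, made from 3, 10 and 30 ng. At 10 ng the chosen transcripts held 23511774 tags in the high-volume library and 26826267 in the low-volume library. At 3 ng they held 14160401 and 15920967, and at 30 ng 25867706 and 31524211. The 3 ng library was thus the shallowest of each volume.

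The ganglia were rich in transcripts of sensory neurons. Among the neuronal genes, Sncg (gamma-synuclein) had a mean RPKM of 4956 ± 722 (SD, n = 6 libraries), Tubb3 (neuronal beta-tubulin) 2961 ± 501, Stmn2 1292 ± 34.3, Nefl (neurofilament light chain) 573 ± 73.6 and Prph (peripherin) 359 ± 47.7. Of the 19 sensory neuron genes in the files, 16 had a mean RPKM of 10 or more. Isl1, a homeobox gene of sensory neuron identity, was at 129 ± 17.9 and its partner Pou4f1 (Brn3a) at 48.5 ± 12.1.

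Several genes of the nociceptor lineage, the neurons that sense pain and temperature, were abundant. Gal (galanin) had a mean RPKM of 1558 ± 193, Gfra3 95.4 ± 16.1, P2rx3 83.4 ± 14.4 and Tac1 (substance P precursor) 43.5 ± 4.65 (SD, n = 6). Of the 14 nociceptor genes 9 reached an RPKM of 10 and 1 was under 0.1, and of the 14 genes of the mechanoreceptor and proprioceptor lineage 3 reached 10, a difference that was not tested: Pvalb at 52.9 ± 8.73, Cbln2 at 15.9 ± 5.37 and Etv1 at 15.8 ± 3.08. Ntrk3 (TrkC) was at 5.13 ± 1.42 and Ntrk2 (TrkB) at 3.13 ± 0.247.

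On the log2(RPKM + 1) scale Runx1 exceeded Runx3 by 0.65 ± 0.19 (SD, n = 6), Isl1 exceeded Pou4f1 by 1.42 ± 0.27 and the sodium channel gene Scn9a exceeded Scn10a by 0.80 ± 0.32, each in 6 of 6 libraries. The log2 difference was -1.43 ± 0.33 for Calca (the precursor of CGRP) minus Tac1, -3.20 ± 0.30 for Sox10 minus Isl1 and -0.67 ± 0.26 for Prph minus Nefl, and in these pairs the first gene was higher in 0 of 6 libraries. Each of these 6 pairs had an exact sign-flip p of 0.0312, the smallest the test can give, and an adjusted p of 0.0352 over 9 pairs. Ntrk2 minus Ntrk3 was -0.53 ± 0.39 with an exact p of 0.0625, which missed the threshold, and with CPM in place of RPKM it was 0.68.

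Among the other cells of the ganglion, glial genes were led by Fabp7, a fatty acid binding protein of immature glia, with an RPKM of 869 ± 48.6, followed by Ednrb at 70.5 ± 12.7 and Pmp22 at 69.5 ± 10.4 (SD, n = 6). Sox10, the glial transcription factor, was at 13.1 ± 1.51. Of the 25 cell cycle genes, 24 had an RPKM of 1 or more, with Ube2c at 33.7 ± 3.29 and Pcna at 30.5 ± 3.92. Embryonic globin Hbb-y reached 3034 ± 245 and Hbb-bs 1125 ± 112. Vessel genes were present with Ramp2 at 86.4 ± 5.28, Egfl7 at 27.6 ± 2.90 and Pecam1 at 6.85 ± 1.48, although 73.1% of the length of the Ramp2 transcript was shared with another gene. Fibroblast genes included Dcn at 92.6 ± 10.7, Col1a2 at 61.6 ± 3.24 and Col3a1 at 52.6 ± 3.92, and pericyte and smooth muscle genes were led by Acta2 at 12.2 ± 1.83. The macrophage genes Tyrobp and C1qb were at 68.4 ± 9.69 and 54.8 ± 2.73.

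As lists, markers of neighbouring tissues had low medians, with a median RPKM of 0.794 for cartilage and bone, 0.601 for skeletal muscle, 0.0953 for spinal cord, 0.118 for sympathetic and chromaffin cells and 0.642 for epidermis, while single members were higher. The cartilage gene Cnmd had an RPKM of 47.3 ± 8.72 and Col2a1 2.99 ± 1.15, and the muscle genes Mylpf and Acta1 were at 22.0 ± 3.51 and 10.1 ± 1.37 (SD, n = 6). Of the 18 spinal cord genes, 1 reached an RPKM of 1, Hes5 at 5.85 ± 3.73, and 9 were under 0.1. Olig2 of motor neuron progenitors had 0 or 1 tags in each library. Th (tyrosine hydroxylase) was at 180 ± 25.1 and Chga at 26.8 ± 4.83, whereas the sympathetic gene Dbh was at 0.118 ± 0.162. The epidermal genes Krt10 and Cdh1 were at 4.65 ± 1.02 and 3.38 ± 1.35. Among the Hox genes Hoxa7 was highest at 26.9 ± 3.73, followed by Hoxb7 at 10.8 ± 1.35, and 20 of 32 had an RPKM of 1 or more.

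**Figure D1:**
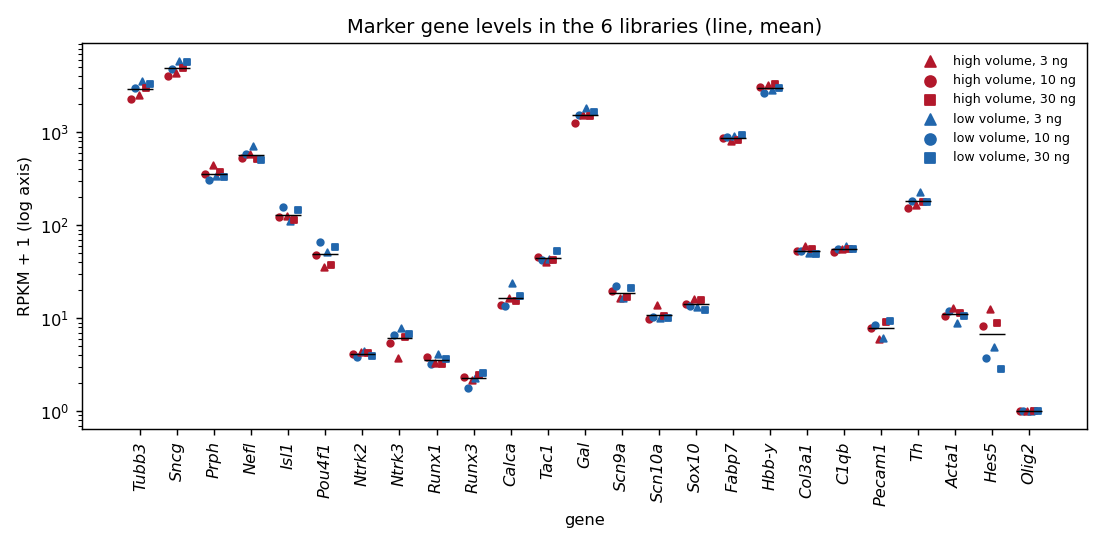
RPKM + 1 on a log axis for marker genes of neurons, glia, blood, vessels, connective tissue and neighbouring tissues, with 1 point per library, colour for the reaction volume, symbol for the input and a line at the mean of 6 libraries. Gal had a mean RPKM of 1558, Ntrk2 of 3.13 and Ntrk3 of 5.13, and Hes5 had higher values in the 3 high-volume libraries.

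The most abundant transcript was Gm42418 (ENSMUSG00000098178, chromosome 17, 39846958 to 39848788), a noncoding RNA gene known from other work to contain ribosomal RNA sequence, with 6.01% of all tags. Pooled over the libraries it was followed by mt-Co3 with 2.26%, Lars2 with 1.74%, mt-Atp6 with 1.59%, mt-Rnr2 with 0.917%, Actb with 0.875%, mt-Co1 with 0.861%, mt-Cytb with 0.804%, mt-Nd1 with 0.690% and Tmsb4x with 0.651%. The order differed between libraries, and mt-Atp6 exceeded Lars2 in 4 of 6. Of these 10 genes 6 belonged to the mitochondrial genome.

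The comparison of reaction volumes asked which transcripts were counted differently when the same RNA was reverse transcribed in the larger or the smaller reaction. Gm42418 was higher in the high-volume libraries, with 91970 ± 12007 CPM (SD, n = 3) against 33881 ± 2102 CPM in the low-volume libraries, a log2 difference of 1.56 ± 0.11 (SE, edgeR adjusted p = 0.0142). It was the only gene past the threshold among 16120, and 1076 genes had an unadjusted p under 0.05. It was named after its values were seen, because the rule for named genes leaves out such symbols. Ribosomal protein genes, histone genes and Hox genes also lay above other genes as lists with the preset correlation, and the lists of neurons, glia and other cell types did not pass in the 6 libraries. With an estimated correlation none of the 3 lists passed (camera adjusted p = 0.530, 0.418 and 0.418 with an estimated correlation). That correlation was 0.515 for the ribosomal protein list, -0.0294 for the histone list and -5e-04 for the Hox list. For histones and Hox genes it lay below the preset of 0.01, so a higher correlation between genes was not what raised their p. With an estimated correlation camera uses the 3 residual degrees of freedom of the fit, which by itself raises p. For the ribosomal protein list the higher correlation raises it too. With the input as a replicate block 0 genes passed in edgeR (lowest adjusted p 0.249), DESeq2 called 182 genes (92 higher, 90 lower), and without low-volume replicate 2, the 3 ng library, 0 genes passed.

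The fit of the 10 and 30 ng libraries alone, set before the data were seen, called 274 genes, 200 higher and 74 lower in high volume, with 1 residual degree of freedom. On simulated counts this fit gave 20 false calls among 210, a share above the threshold. In the same libraries with the block and a GC correction, chosen after the data were seen, 193 genes were higher and 195 lower, so the excess of higher genes was not kept. Among the higher genes were Iscu (an iron-sulfur cluster scaffold) with a log2 difference of 2.11 ± 0.22 (SE, edgeR adjusted p = 0.00211), Chchd10 of the mitochondrial intermembrane space at 2.06 ± 0.23, the neuroendocrine gene Pcsk1n at 1.92 ± 0.19, the Mediator subunit Med30 at 1.75 ± 0.20 and Ndfip1 at 1.63 ± 0.12. Raly, Sf3a2, Ube2s, Prpsap1 and Chtf8 were also in this set, and so was the globin Hba-a1, whose tags can be split with its near-identical copy Hba-a2. Chtf8 shares exonic bases with a second gene entry of the same name, and 19.4% of the length of the Sf3a2 transcript is shared with Plekhj1. In the 6 libraries Iscu had 17.8 ± 2.09 CPM (SD, n = 3) in high volume and 4.50 ± 0.626 in low volume, and its edgeR adjusted p over all 6 libraries was 0.327. Lower genes included Znrf3 at -0.91 ± 0.20, Nup85 at -0.72 ± 0.13, Cavin1 (a component of caveolae) at -0.68 ± 0.09 and Ado at -0.66 ± 0.10. Pan2, Ankrd27, Usp37, Kitl, Slitrk2 and Pdcl belonged to the lower set, as did Slc24a5 and Myef2, which share exonic bases with each other. Cavin1 had 139 ± 7.16 CPM (SD, n = 3) in high volume and 249.5 ± 15.1 in low volume. In the 3 ng pair, which this fit did not use, 159 of the 200 higher genes were higher and 10 of the 74 lower genes were higher in high volume. Of the genes named here, the lower genes Kitl (0.61), Pdcl (0.24) and Ankrd27 (0.09) and the higher gene Hba-a1 (-0.02) had the opposite sign in that pair. The other genes named in this paragraph kept their sign.

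**Figure D2:**
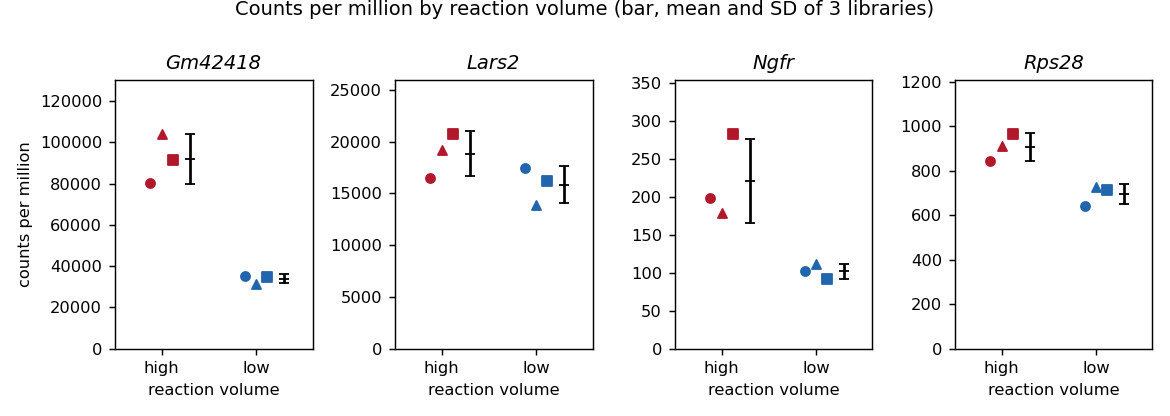
CPM of Gm42418, Lars2, Ngfr and Rps28 in the high-volume (red) and low-volume (blue) libraries, with 1 point per library (triangle 3 ng, circle 10 ng, square 30 ng) and a bar for the mean and SD of 3 libraries. Gm42418 was at 91970 ± 12007 CPM in high volume and 33881 ± 2102 CPM in low volume, and Lars2, at 18819 ± 2178 and 15828 ± 1811 CPM, overlapped between the volumes.

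Genes of sensory neuron types mostly differed little between the volumes. Of the 19 measured sensory neuron genes, 0 passed over all 6 libraries and 0 when adjusted over the list alone, with a median log2 difference of 0.03 that turned to -0.10 under total-count scaling (camera adjusted p = 0.827). Tubb3 was at -0.21 ± 0.11 (SE) and Sncg at -0.15 ± 0.11. In the 10 and 30 ng libraries Prph was higher in high volume (0.33 ± 0.07, edgeR adjusted p = 0.0425) and Pou4f1 lower (-0.45 ± 0.09, adjusted p = 0.0312). With the GC correction in these libraries Prph lost that difference, at -0.04, while Tubb3 at -0.38 (edgeR adjusted p = 0.00167) and Sncg at -0.24 (adjusted p = 0.0240) were lower in high volume. The nociceptor list (12 genes, median -0.09, camera adjusted p = 0.866) held 1 gene that passed when adjusted over the list alone, Ngfr, the p75 neurotrophin receptor (chromosome 11, 95568818 to 95587735). In the 10 and 30 ng libraries the median of this list turned to 0.04. Ngfr had 220.5 ± 55.5 CPM (SD, n = 3) in high volume and 102.0 ± 9.93 CPM in low volume, with a log2 difference of 1.21 ± 0.18 (SE) and 1.40 ± 0.13 without the 3 ng libraries (edgeR adjusted p = 0.00176). Gal was at -0.07 ± 0.11. Of the 13 mechanoreceptor and proprioceptor genes (median -0.06, camera adjusted p = 0.866), Cbln2 passed over the list alone at 0.81 ± 0.15, while Etv1 was at -0.32 ± 0.13 and Piezo2 at 0.26 ± 0.14.

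The glial list (16 genes, median 0.11, -0.01 under total-count scaling, camera adjusted p = 0.807) held Ngfr as its 1 gene past the threshold over the list alone, while Fabp7 was at 0.02 ± 0.08 and Ednrb at -0.27 ± 0.10 (SE). No gene passed, over all genes or the list alone, among 25 cell cycle genes (median -0.07, camera adjusted p = 0.142; Tyms -0.07 and Mcm6 -0.02), 15 endothelial genes (0.18, 0.208; Ramp2 0.14, Egfl7 0.23), 16 fibroblast and meningeal genes (0.04, 0.868; Col1a2 0.07, Col3a1 0.30) or 8 pericyte and smooth muscle genes (0.11, 0.560; Acta2 0.48, Rgs5 -0.25). The same held for 15 macrophage genes (0.00, 0.866; C1qb 0.08, Tyrobp -0.10), 10 cartilage and bone genes (0.29, 0.142; Cnmd 0.01, Col11a1 -0.21) and 12 skeletal muscle genes (0.29, 0.142; Mylpf 0.04, Acta1 0.32). It also held for 7 sympathetic and chromaffin genes (-0.05, 0.955; Th -0.09, Chga 0.30) and 7 epidermal genes (-0.52, 0.546; Cdh1 -0.86, Krt10 0.50). Total-count scaling moved the median of all genes from 0.02 to -0.10, and with it the medians of the fibroblast, pericyte, macrophage and oxidative phosphorylation lists to below 0. Of 11 erythroid genes (median 0.31, camera adjusted p = 0.142), Hbb-y at 0.33 ± 0.08 and Hbb-bs at 0.31 ± 0.09 passed over the list alone. Of 7 spinal cord genes (median 0.12, camera adjusted p = 0.293), Hes5, a target of Notch signalling, passed over the list alone at 1.85 ± 0.33, and Pax6 was at -0.87 ± 1.41. The Hes5 transcript shares 34.0% of its length with Gm20421.

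The 80 cytosolic ribosomal protein genes lay higher in high volume as a list, with a median log2 difference of 0.26, 78 members above 0 and a camera adjusted p of 1.47e-10. The adjusted p was 0.530 with an estimated correlation. Over all genes 0 of these genes passed, and adjusted over the list alone 38 were higher and 1, Rpl4, was lower. Rps10 was at 0.54 ± 0.10 (SE) and Rps28 at 0.51 ± 0.10, with 908 ± 61.7 CPM for Rps28 in high volume and 695 ± 44.8 CPM in low volume (SD, n = 3). In the 10 and 30 ng libraries Rps10 fell from 0.48 to 0.14 with the GC correction and lost its call (edgeR adjusted p = 0.339), and Rps28 kept it at 0.47. Rpl41 was at 0.38 ± 0.12 and Rps14 at 0.15 ± 0.11, and Rpl4 was at -0.29. Rps29 and Rpl27a were among the 25 ribosomal protein genes higher in the 10 and 30 ng libraries, where 1, Rpl4, was lower. Of 24 replication-dependent histone genes, whose mRNAs end in a stem-loop and lack a poly(A) tail, 16 were above 0, with a median of 0.56 (camera adjusted p = 0.00288). The adjusted p was 0.418 with an estimated correlation. Hist1h1e at 1.07 ± 0.23 and Hist1h4d at 0.89 ± 0.17 passed over the list alone, Hist3h2ba was past the threshold in the 10 and 30 ng libraries, and Hist3h2a was at -0.13 ± 0.18 over 6 libraries. The Hist3h2a transcript shares 35.6% of its length with Trim17. Most histone genes were low: of 65 in the files, 16 had a mean RPKM of 1 or more and 21 were under 0.1. Of 30 Hox genes, which encode position along the body axis, 26 were above 0, with a median of 0.29 (camera adjusted p = 0.00961). The adjusted p was 0.418 with an estimated correlation, and 0 Hox genes passed over all genes or the list alone. The members with the highest CPM were at 0.01 ± 0.16 (Hoxa7) and 0.27 ± 0.30 (Hoxa10).

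The remaining lists did not pass in the 6 libraries. The 12 protein-coding genes of the mitochondrial genome had a median of 0.22 (camera adjusted p = 0.178), with mt-Co3 at 0.54 ± 0.11 (SE) and mt-Co1 at 0.35 ± 0.09 past the threshold over the list alone and mt-Atp6 at -0.12 ± 0.18. In the 10 and 30 ng libraries this list passed after the GC correction (median 0.36, camera adjusted p = 0.00169) and not before it (0.14, 0.494), both with the preset correlation. The estimated correlation of this list was 0.963 in the 6 libraries, far above the preset. Without the GC correction its camera adjusted p = 0.954 with an estimated correlation in the 10 and 30 ng libraries. With 1 residual degree of freedom that version can hardly call a list, so this value decides little. The corrected list was run with the preset correlation only, so it was not tested whether the call holds with an estimated one. The 80 nuclear genes of oxidative phosphorylation were at 0.07 (0.142), with Ndufa4 at 0.18 ± 0.08 and Atp5o at -0.02 ± 0.08, and Atp5d was higher in the 10 and 30 ng libraries (0.42) but not with the GC correction there (0.13, edgeR adjusted p = 0.375). The 21 small structured RNA genes were at 0.25 (0.178), with Snord13 at 0.77 ± 0.29 and Rn7sk at 0.00 ± 0.27. The 17 immediate-early and stress genes were at 0.38 (0.0530), with Hspa8 at -0.31 ± 0.07 and Dnajb1 at 0.12 ± 0.15, and the 9 nuclear long noncoding RNAs at 0.33 (0.0530), with Malat1 at -0.09 ± 0.12 and H19 at 0.21 ± 0.09. The 16 reference genes were at -0.03 (0.866), with Actb at -0.12 ± 0.06 and Eef1a1 at -0.14 ± 0.06.

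**Figure D3:**
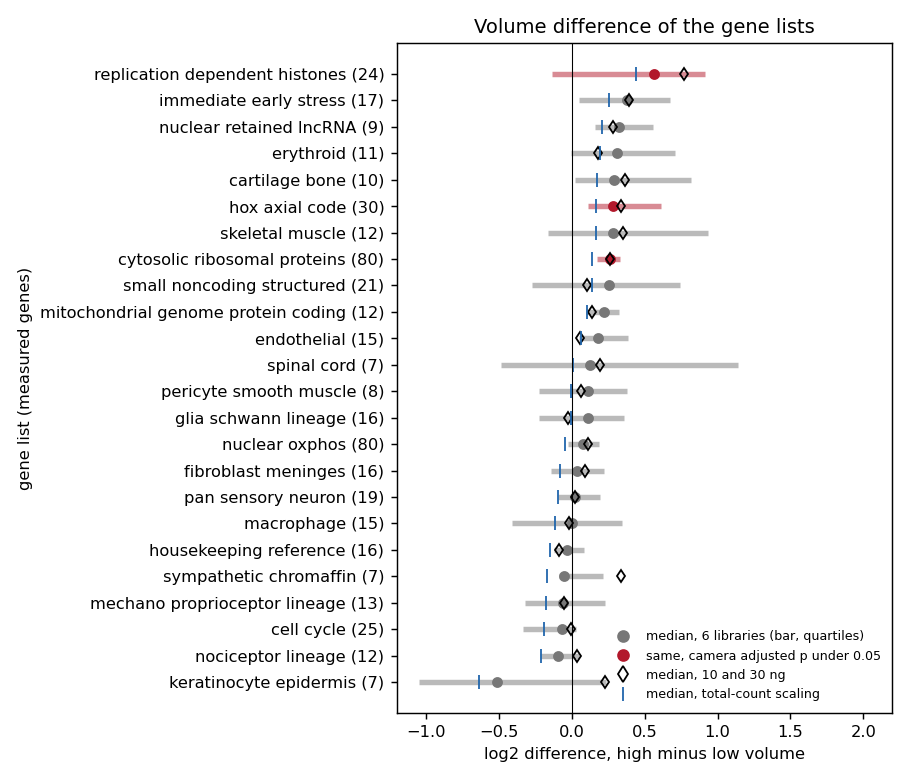
Median log2 difference, high minus low volume, of the 24 gene lists, with the quartiles of their genes as bars, and the medians in the 10 and 30 ng libraries (diamonds) and with total-count scaling (blue ticks). The ribosomal protein, histone and Hox lists (red), at 0.26, 0.56 and 0.29, had a camera adjusted p under 0.05 with the preset correlation and not with an estimated correlation, and medians near 0 changed sign with total-count scaling.

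Genes higher in high volume in the 10 and 30 ng fit had a median GC content of 57.8%, those lower 46.5%, and all tested genes 50.1%. Across 10863 genes with a mean CPM of 5 or more, Spearman's rho of GC content with the log2 volume difference was 0.402 in the 10 and 30 ng libraries, 0.162 in the 10 ng pair, 0.542 in the 30 ng pair and 0.00450 in the 3 ng pair. Genes are not independent replicates, so no p is given for these values.

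The input comparison asked which transcripts changed their share with the amount of RNA. No gene passed over 6 libraries with edgeR (lowest adjusted p 0.355), 1252 genes had an unadjusted p under 0.05 and DESeq2 called 44. The lowest p belonged to Gm23935, a small RNA gene, which was named after its values were seen. Its log2 change per doubling of input was -0.40 ± 0.04 (SE). Hba-a1, at -0.75 ± 0.13 per doubling (edgeR adjusted p = 0.625), and Gm23935 were the 2 genes past the threshold without the filter on low counts. In the 10 and 30 ng libraries the 1 gene called was Hba-a2 at -0.53 ± 0.06. These globin copies can share reads. No list of the 24 passed for input (lowest camera adjusted p 0.507), and the list medians per doubling ran from -0.11 for 7 sympathetic genes to 0.28 for 7 spinal cord genes. The medians were -0.01 for 19 sensory neuron genes (camera adjusted p = 0.520), -0.03 for 12 nociceptor genes (0.632), 0.02 for 80 ribosomal protein genes (0.961), 0.04 for 24 histone genes (0.851) and -0.01 for 30 Hox genes (0.851). Adjusted over the list alone, Cbln2 and Hba-a1 had lower values with more input, and no other list member passed.

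The interaction asked whether the volume difference changed with the input. No gene passed with edgeR (lowest adjusted p 0.583), 1347 had an unadjusted p under 0.05, DESeq2 called 17 genes and edgeR without the filter on low counts called 254. The 5 genes with the lowest p were Prpf19 (a splicing factor), Ndfip1, Akr7a5, Med16 and Pfkfb1. For Prpf19 the log2 difference between volumes was -1.82 at 3 ng, -0.18 at 10 ng and 0.55 at 30 ng, with an interaction of 0.71 ± 0.12 (SE) per doubling. For Ndfip1 it was 0.31, 1.39 and 1.86, and the interaction was 0.47 ± 0.09.

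Fewer genes were detected in the 3 ng libraries, and between 10 and 30 ng the counts differed about as little as between the volumes. After thinning to equal depth, 16639 and 16544 genes had 5 or more tags in the high- and low-volume libraries of 10 ng, 16677 and 16612 at 30 ng, and 15288 and 15010 at 3 ng. The mean was 16201 ± 791 (SD, n = 3) in high volume and 16056 ± 906 in low volume (two-sided exact permutation p = 0.5). This test does not use the pairing by input. Within the pairs of the same input, gene detection and the share of ribosomal protein genes were higher in high volume in 3 of 3 pairs. The 100 most abundant genes took 36.8 ± 0.603% of tags in high volume and 30.9 ± 0.995% in low volume (n = 3, exact permutation p = 0.1, the smallest possible), and Gm42418 alone took 9.20 ± 1.20% and 3.39 ± 0.210% (exact permutation p = 0.1). The differences were 5.88 and 5.81 percentage points, and Gm42418 is among the 100 genes. All shares sum to 100%, so a larger share of Gm42418 lowers those of the other genes. Whether the other abundant genes also differed as a share of the tags outside Gm42418 was not tested. Mitochondrial genes took 9.13 ± 1.86% and 8.11 ± 0.975% (exact permutation p = 0.5, n = 3), ribosomal protein genes 8.29 ± 0.360% and 7.73 ± 0.421% (p = 0.3), and histone genes 0.0235 ± 0.00120% and 0.0193 ± 0.00141% (p = 0.1). Introns held 3.28 ± 0.259% and 3.19 ± 0.398% of tags (exact permutation p = 0.8, n = 3). The log2 ratio of 5′ to 3′ coverage was -0.44 ± 0.12 in high volume and -0.44 ± 0.02 in low volume (exact permutation p = 1.0, n = 3). Over the 9 measures the lowest adjusted p was 0.3.

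The 3 ng libraries stood apart from the rest. Across the tested genes, Pearson's r of log2 CPM was 0.974 to 0.984 for the 6 pairs among the 10 and 30 ng libraries and 0.840 to 0.910 for the 9 pairs with a 3 ng library. The lowest value, 0.840, was between both 3 ng libraries. The median r was 0.908 within a volume and 0.902 between volumes, and 0.981 and 0.977 among the 10 and 30 ng libraries. The coefficient of variation between libraries from edgeR was 0.391 over 6 libraries and 0.144 without the 3 ng libraries. Prpf19 was at 29.9 TMM-scaled CPM in the high-volume and 105.7 in the low-volume 3 ng library, against 78.1 and 88.6 at 10 ng.

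**Figure D4:**
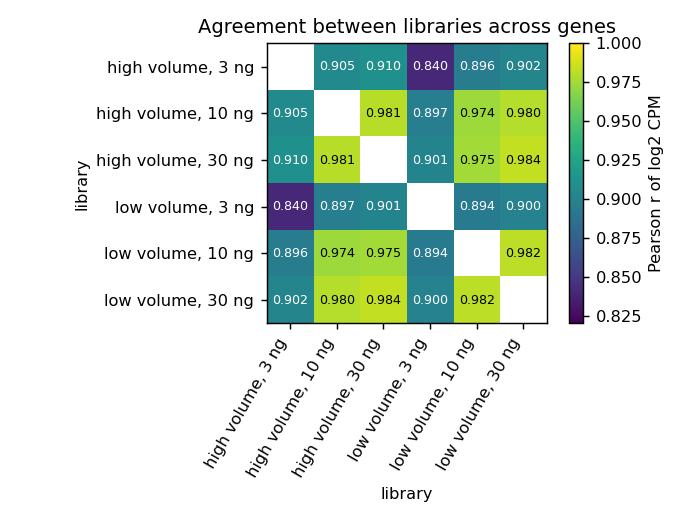
Pearson's r of log2 CPM across genes for the 15 pairs of libraries, with the libraries on both axes and r as colour and number. Pairs of 10 and 30 ng libraries were at 0.974 to 0.984, and pairs with a 3 ng library were at 0.840 to 0.910.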

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

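Signal was present in rows that the gene comparisons did not use. Transcripts with no gene in the annotation used held 2.53% of transcript tags in the lowest and 2.75% in the highest library. Lars2, a mitochondrial leucyl-tRNA synthetase (ENSMUSG00000035202, chromosome 9, 123366940 to 123462664), ranked among the most abundant genes, but its last exon, chromosome 9, 123461499 to 123462664, held 99.85% of its tags in the lowest and 99.96% in the highest library. The other 20 of its 21 exons held 6.85 to 20.3 CPM. Groups of 3 libraries are too small for a test of single libraries.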

How the results depend on the processing

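Voom with quality weights, the fit without Gm42418, the GC correction, input in the 10 and 30 ng libraries and camera with the block or in those libraries were chosen after seeing the data, and the cause of a changed value was not tested unless said. Gm42418 was higher in high volume under all 21 alternatives that kept it (log2 1.06 to 1.66) and past the threshold in 18. For volume, against 1 gene, 11 were called with no filter on low counts, 182 with DESeq2 (9688 genes without an adjusted p), 0 with the replicate block, 0 with the block and length correction, 0 without Gm42418, 274 in the 10 and 30 ng libraries, 260 with quality weights and 388 in the 10 and 30 ng libraries with the block and GC correction. Leaving out 1 library gave 0 (without low-volume replicate 2) to 2 genes (without high-volume replicate 3, Gm42418 and mt-Co3). Of the 274 calls in the 10 and 30 ng libraries, 223 were shared with quality weights, 190 with the GC correction and 118 with DESeq2, all in the same direction. For input, against 0 genes, 2 were called with no filter, 44 with DESeq2 and 1 in the 10 and 30 ng libraries. For the interaction, against 0, 254 were called with no filter and 17 with DESeq2. Leaving out any library called 0 genes for input and 0 for the interaction. For the lists, against 3, camera with an estimated correlation called 0, fry 5 (endothelium, cartilage, skeletal muscle, histones and immediate-early genes, but neither ribosomal proteins nor Hox genes), camera in the 10 and 30 ng libraries 5 (the 3 lists, skeletal muscle and immediate-early genes), and 0 there with an estimated correlation. Fry tests against no change, so its count answers another question. Camera with an estimated correlation has 3 residual degrees of freedom in the 6 libraries and 1 in the 10 and 30 ng libraries. Its counts of 0 therefore decide little. With the GC correction there and the preset correlation, the 3 lists and the mitochondrial genome list (adjusted p = 0.00169, and without the GC correction adjusted p = 0.954 with an estimated correlation) passed, and skeletal muscle (0.0958) and immediate-early genes (0.563) did not. The corrected lists were not run with an estimated correlation. With the length correction skeletal muscle (0.0859) did not. The block changed no list call. The longest-transcript RPKM left all 9 gene pairs as they were, since it chose the same transcripts.

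Ntrk2 minus Ntrk3 turned to 0.68 with CPM. Among named genes, none of them called in the fit of 6 libraries, the sign turned by more than 1 SE as follows. In the 10 and 30 ng libraries Cnmd was at -0.33, Col11a1 at 0.0614, Hoxa10 at -0.0568 and Hist3h2a at 0.0896, and with the block and GC correction Cnmd was at -0.29, Col11a1 0.11, Hoxa10 -0.0931, Hist3h2a 0.16, Prph -0.0393, Ramp2 -0.11, Rgs5 0.18, C1qb -0.11 and Acta1 at -0.0776. Quality weights put Cnmd at -0.25, Hoxa10 at -0.10 and Hist3h2a at 0.0579. Fabp7 was at -0.0778 with the block and length correction and -0.10 with total count, which put Col1a2 at -0.0524. With 1 library left out, the lowest and highest values were, for Kitl, -0.794 (without low-volume replicate 2) and 0.0308 (without high-volume replicate 3), Rgs5 -0.589 and 0.0808, Cnmd -0.31 and 0.151, Col11a1 -0.375 and 0.0490 (each without high-volume replicate 1 or 2), Pax6 -3.16 (without high-volume replicate 1) and 1.79 (without low-volume replicate 1), mt-Atp6 -0.353 (without high-volume replicate 1) and 0.11 (without high-volume replicate 3), Hoxa10 -0.0521 and 0.607 (without low-volume replicate 2 or high-volume replicate 3) and Malat1 -0.224 and 0.0554 (the same 2 libraries). Without low-volume replicate 2 Cnmd was at -0.24 and Hist3h2a at 0.0544. The other 1745 values of named genes kept their direction and side of the threshold, 154 passed it in an alternative and 3 lost it.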

Other observations

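The tests of GC content, length, scaling, RNAs without a poly(A) tail, a shared shift at 3 ng and other splits of the libraries were chosen after the results were seen, while those of depth and of chance loss at 3 ng were set before. After the values were seen, the rule for RNAs without a poly(A) tail was made stricter, and the deciding value for chance loss was moved from the overlap of lost genes to the slope, because an overlap of 0 with 0.429 expected has no power. All libraries come from 1 pool, so the design gives no biological explanation of any difference between them, and none was tested.

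The pool held RNA of both sexes: Xist, expressed from the inactive X chromosome, had an RPKM of 2.37 ± 0.485 (SD, n = 6), and the Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were at 5.17 ± 1.74, 6.56 ± 0.798, 2.59 ± 0.782 and 1.24 ± 0.534. The imprinted RNA H19 was at 213 ± 11.3. Gm26917, which lies beside Gm42418 on chromosome 17, was at 203.7 CPM in the high-volume 3 ng library and at 8.01 to 25.2 CPM in the other 5.

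Gm42418 was higher in the high-volume libraries by 1.56 on the log2 scale. Scaling alone did not account for it, since the difference was 1.44 ± 0.10 (SE) with total counts. A general gain of RNAs without a poly(A) tail stays open: the median of the small structured RNA genes was 0.25, with an upper quartile of 0.75, and the upper quartile of the histone genes was 0.92. Lars2, whose tags lie in the last exon, was at 18819 ± 2178 CPM (SD, n = 3) in high and 15828 ± 1811 CPM in low volume. Of the 10 splits of the 6 libraries into 3 and 3, the real split called 1 gene and the highest other split 0, and 10 splits are too few for a share under 0.05.

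The 3 ng libraries lay apart from the 10 and 30 ng libraries. Depth did not account for it: thinned to the smallest library, the pairs of 10 and 30 ng libraries still had r of 0.973 or more, and pairs with a 3 ng library 0.919 or less. A shift of the same genes in both 3 ng libraries did not account for it either, with r = 0.0924 across 10884 genes between their shifts. Chance loss of scarce transcripts is a candidate explanation: the extra squared variation fell with expression with a slope of -0.794 in the high-volume and -0.798 in the low-volume 3 ng library, against -0.432 to -0.220 in the other 4. Among genes above 5 CPM, 20 and 34 had no tag in the high- and low-volume 3 ng library and 0 in both, but 0.429 were expected to coincide by chance, so this overlap decides nothing, and uneven amplification was not tested.

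Ribosomal protein, histone and Hox genes were higher in the high-volume libraries as lists with the preset correlation, and none passed with an estimated correlation (camera adjusted p of 0.418 or more in the 6 libraries and 0.806 in the 10 and 30 ng libraries). That version has 3 residual degrees of freedom in the 6 libraries and 1 in the 10 and 30 ng libraries. It had little power, so these values decide little about the lists. In the 10 and 30 ng libraries with the preset correlation, 3 of the 3 lists kept a camera adjusted p under 0.05 after each correction. Their medians stayed above 50% of those before. By this rule, chosen after the results were seen, neither GC content nor transcript length alone accounted for the whole difference. A part for either stays open, since several medians fell and the corrected lists were not run with an estimated correlation. The ribosomal protein median was 0.27 before, 0.21 after the GC and 0.15 after the length correction, the histone median 0.71, 0.37 and 0.59, and the Hox median 0.33, 0.27 and 0.34. Of the 10 splits, which are too few for a share under 0.05, 4 called 3 or more lists, the real split called 3 and the highest other split 5. Among the 4 splits that part all 3 inputs the others called 0 or 1.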
